A study of Mus musculus with 10 samples.

How the data were processed

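RNA from frozen, homogenised whole mouse liver was measured in 10 libraries on the BGISeq-500 sequencer. The labels put 5 libraries in a group called Alk1-HEC-KO and 5 in a control group, and the series title names Alk1, another name of Acvrl1, as the gene knocked out in mice. The letters HEC are not spelled out in the labels. Nothing in the labels says that the 5 libraries of a group came from separate animals, so p-values measure the spread between these libraries.

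Each library had a deposited table of estimated counts per gene and a deposited table of TPM (transcript abundance scaled to the same sum in every library) per gene, both over 55385 versioned Ensembl gene IDs. The submitters' processing notes name Trim Galore 0.6.4, kallisto 0.4.6 and the mouse build GRCm38.p6, without saying how transcript estimates were brought to genes or whether strand was used. The TPM deposited by the authors were used for levels, and the estimated counts deposited by the authors for the tests. Of the nonzero estimated counts, 38.3% were whole numbers within 1e-06, and all were rounded to whole numbers, which changed no library total by more than 0.0008%. Totals ran from 20.91 to 21.56 M (mega) counts per library. Symbols and coordinates came from a GRCm38 gene annotation, which matched 55144 IDs. The other 241 IDs held at most 0.013% of the counts of a library.

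Genes were kept with the default count filter of edgeR, filterByExpr with the group, which left 12872 tested genes. Counts were scaled by TMM (factors from 0.869 to 1.107) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, group as the only term). P-values were adjusted by the Benjamini-Hochberg method, and a gene was called when its adjusted p was under 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F. Fold changes are given for libraries labelled Alk1-HEC-KO over control libraries. The biological coefficient of variation was 0.272.

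Before the data were examined, 36 gene lists were fixed for the liver's cell types, zones and functions and for signs of handling. Each list with at least 5 tested members, 33 in all, was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with a correlation estimated per list, and the self-contained test fry, were run beside it. Members of a list are counted by their adjusted p over all genes and, separately, adjusted over the list alone. A list's score in a library is the mean log2 CPM of its tested members, and scores were compared by exact two-sided permutation tests, whose smallest possible p with 5 against 5 libraries is 0.0079.

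The genes named in the text were set by a rule fixed before the data were examined. It takes Acvrl1, then the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change among those with a mean of at least 1 TPM in the higher group and no overlap of the groups in log2 CPM, leaving out predicted genes named Gm or Rik, pseudogenes, IDs without a symbol, Y-linked genes and Xist. It adds every tested member of the endothelial angiocrine and BMP target lists, and from each other list with a called member up to 4 members with the smallest adjusted p plus the most abundant one. The 7 untested members of the angiocrine and BMP target lists lie outside the rule and were taken up after their values were seen, as were Ly6c2, Saa1, Fos, Vwf and the genes that open the closing observations.

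The tests were checked on simulated counts drawn from the means, dispersions and library sizes of these 10 libraries, with 200 genes changed. In that simulation of 5 against 5 libraries over 12712 tested genes, edgeR recovered 10% of genes changed 1.5-fold, 64% of those changed 2-fold, and 90% of those changed 4-fold and 8-fold. It called 130 genes, of which 3 had not been changed, while DESeq2 called 153 with 20 not changed. Simulated genes were drawn independently of each other, so the simulation does not check the tests of lists. For genes with few counts, ratios of group totals carry 95% exact binomial intervals, which cover counting error only.

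Alternatives covered leaving out each library, the replicate number as a block, other scalings, filters, tests and thresholds, limma on log2(TPM + 1) and log2(TPM + 0.1), and the run of consecutive numbers in the deposited file names as a covariate. The deposited names fall into 3 such runs. The first holds 2 control libraries and 1 labelled Alk1-HEC-KO, the second 3 and 1, and the third 3 libraries labelled Alk1-HEC-KO. The labels do not say what a run is. With the run as a covariate, libraries of the third run do not bear on the group difference, since that run holds no control. Chosen after seeing the data were offsets for average transcript length and the fits without libraries with Saa1 above 1000 TPM or Fos above 20 TPM. DESeq2 1.42.0 was used only as an alternative. Sex as a covariate was not run because every library had the male pattern.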

Results

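Whole-liver transcript levels were compared between 5 libraries labelled Alk1-HEC-KO and 5 control libraries. ALK1, encoded by Acvrl1, is an endothelial receptor for ligands of the BMP family. Each library held 20.91 to 21.56 M estimated counts, so depth differed little between the groups. The labels state a genotype and no treatment, and the comparison asks how the liver transcriptome differs with that genotype.

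The targeted gene did not show the loss its label names. Acvrl1 (ENSMUSG00000000530.16, chromosome 15, 101128522 to 101145336, GRCm38) averaged 0.669 ± 0.331 TPM in control libraries and 1.36 ± 0.331 TPM in libraries labelled Alk1-HEC-KO (SD, n = 5 each). The control libraries held 1.05, 0.30, 0.39, 0.66 and 0.95 TPM, and the labelled knockout libraries 1.15, 1.39, 1.22, 1.92 and 1.12 TPM. The TPM of the groups did not overlap (exact two-sided permutation p = 0.0079, the smallest that 5 against 5 can give). In log2 CPM they did, with control library 1 at 1.47 and labelled knockout library 2 at 1.43 (exact permutation p = 0.0159). On counts the log2 fold change was 0.99 with a standard error of 0.32, which did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.336). A value for the whole gene does not show whether single exons were deleted. Endothelial cells are a small part of whole liver, and its RNA does not show which cells the transcript came from. Because Acvrl1 goes against the label, the group is called labelled knockout throughout, and every direction below rests on the label.

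Genes of hepatocytes around the central vein were lower in the labelled knockout libraries. Glul, the glutamine synthetase of the innermost pericentral hepatocytes, fell from 283 ± 48.5 to 32.5 ± 10.9 TPM (SD, n = 5), a log2 fold change of -3.24 with a standard error of 0.20 (edgeR, adjusted p = 2.9e-06). The ammonium transporter gene Rhbg fell by a log2 fold change of -3.48 (standard error 0.25), the dicarboxylate transporter gene Slc13a3 from 6.05 ± 2.81 to 0.226 ± 0.0723 TPM, and the glutamate transporter gene Slc1a2 from 24.0 ± 4.85 to 1.17 ± 0.812 TPM. Of the 20 tested members of the pericentral list, none rose, 11 fell over all genes, and 17 fell when adjusted over the list alone. All 20 pointed lower, with a median log2 fold change of -1.63. When libraries were scaled by their totals alone, 19 did. Rcan2 (-1.98, standard error 0.26), Slc22a3 (-2.40, 0.43) and Cyp1a2 (-1.65, 0.30), a caffeine-metabolising cytochrome P450, were among those that fell. Cyp2e1, the most abundant member, averaged 3153 ± 261 TPM in controls and 1658 ± 858 TPM in labelled knockout libraries without passing over all genes (edgeR, adjusted p = 0.17). The list was called lower by camera, also with an estimated correlation (adjusted p = 3.2e-05).

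Targets of WNT and beta-catenin signalling in hepatocytes were lower as well. Of 11 tested members, 5 fell over all genes and 10 when adjusted over the list alone, and all 11 pointed lower under every scaling tried. Axin2, a feedback inhibitor of the pathway, fell from 1.43 ± 0.691 to 0.559 ± 0.226 TPM, the R-spondin receptor gene Lgr5 from 0.767 ± 0.256 to 0.145 ± 0.0989 TPM, and the transcription factor gene Tbx3 from 4.27 ± 0.975 to 1.48 ± 0.469 TPM. Sp5, another transcription factor gene, had 183 counts over the 5 control libraries and 7 over the 5 labelled knockout libraries. Glul, Cyp2e1, Tbx3 and Lgr5 stand in both this list and the pericentral one. The list was called lower with an estimated correlation (camera, adjusted p = 5.6e-05). Tbx3os1, annotated antisense to Tbx3, also fell (-3.14, standard error 0.54), but strand use is not stated, so reads of Tbx3 could count towards it. Tnfrsf19 fell with them (-2.40, 0.36). Hepatocyte genes of the opposite zone gave no called member: among 21 tested periportal genes, none passed and the median log2 fold change was 0.10 (camera adjusted p = 0.17). Of these, 14 pointed higher and 7 lower, or 18 and 3 when scaled by library totals alone. The periportal list was called in 4 of 22 alternatives (camera, lowest adjusted p = 0.0029).

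**Figure D1:**
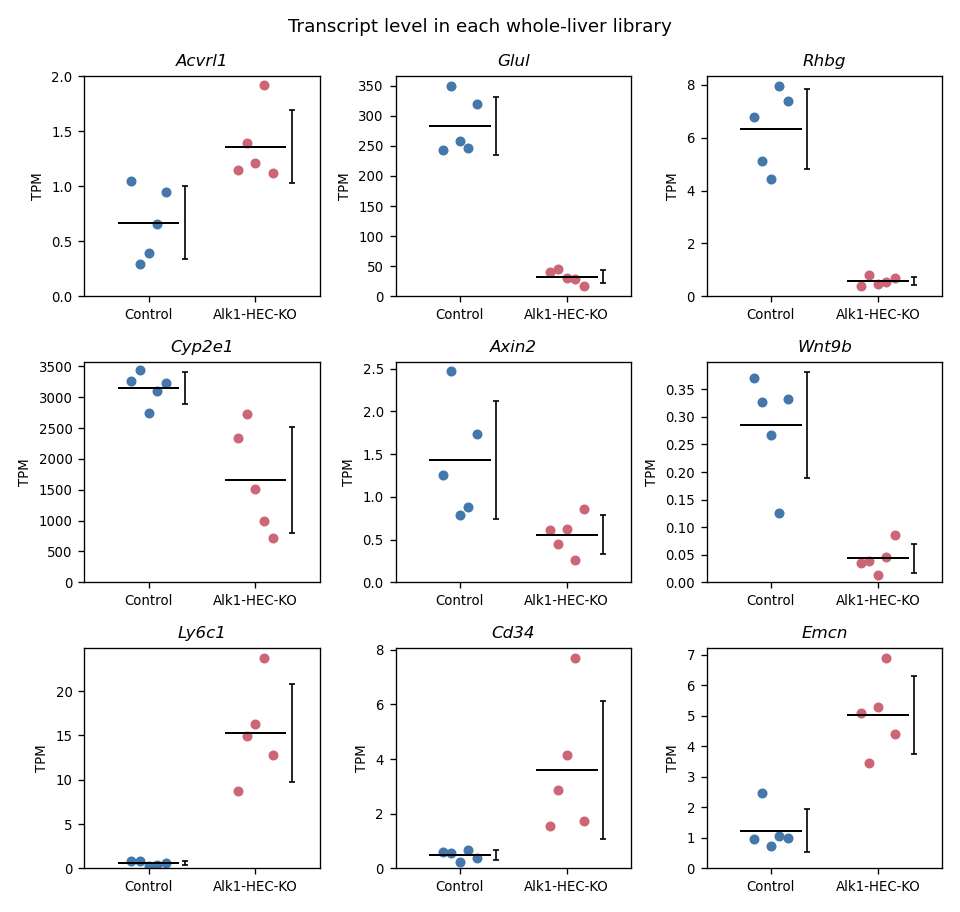
TPM (vertical axis, linear, from 0) of 9 genes in each library, 5 control (blue) and 5 labelled Alk1-HEC-KO (red). Horizontal bars are group means with 1 SD, and Glul, Rhbg, Cyp2e1 and Wnt9b lie lower, and Ly6c1, Cd34, Emcn and Acvrl1 higher, in every labelled knockout library than in every control library.

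Markers of continuous endothelium, the kind lining capillaries and larger vessels, were higher in the labelled knockout libraries. Ly6c1 rose from 0.598 ± 0.267 to 15.3 ± 5.51 TPM (SD, n = 5), a log2 fold change of 5.07 with a standard error of 0.40 (edgeR, adjusted p = 2.7e-05). Its near-identical neighbour Ly6c2, chosen after its values were seen and not tested for lack of counts, averaged 0.528 and 1.27 TPM, and reads of the pair could be split between them. The sialomucin genes Cd34 and Emcn rose from 0.486 ± 0.179 to 3.60 ± 2.52 TPM and from 1.24 ± 0.694 to 5.03 ± 1.27 TPM. Cldn5, a tight junction gene, rose from 3.06 ± 0.873 to 8.29 ± 2.51 TPM, and Cav1, the main caveolar coat gene, from 0.989 ± 0.380 to 3.40 ± 2.10 TPM. Of 13 tested members, 6 rose over all genes. Adjusted over the list alone 10 rose and 1 fell, namely Vwf (-1.16, standard error 0.39), a gene chosen after its values were seen. The most abundant member by its mean over the 2 groups, Aqp1, averaged 16.9 ± 5.90 and 24.7 ± 5.24 TPM and did not pass over all genes (edgeR, adjusted p = 0.55). The list's median log2 fold change was 1.40, and it was called higher with an estimated correlation (camera, adjusted p = 0.021).

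The other endothelial marker lists had no called member, and the tip cell list had 2. The 15 tested sinusoidal markers, which belong to the fenestrated endothelium of the liver, had a median log2 fold change of 0.02, with 8 pointing higher and 7 lower and none called. Scaled by library totals alone, 13 pointed higher and 2 lower. The list was called higher in 2 of 22 alternatives, without the third run of file numbers and without the 2 libraries with high Fos (camera, adjusted p = 0.014 and 0.0021). All 12 pan-endothelial markers pointed higher with a median of 0.78. None of them passed over all genes and 9 rose adjusted over the list alone. That list was called with the preset correlation but not with an estimated one (camera, adjusted p = 0.25 with an estimated correlation). No arterial marker of 9 and no venous marker of 8 passed over all genes, and neither list was called (camera, adjusted p = 0.057 and 0.74). The arterial list was called in 6 of 22 alternatives (camera, lowest adjusted p = 0.0028) and the venous list in 1. Adjusted over the list alone, 3 venous markers rose and 1 fell. Among 16 tip cell and angiogenesis genes, Apln and Pdgfb rose, and 4 rose adjusted over the list alone. Apln, a peptide made by sprouting endothelium, had 269 counts over the labelled knockout libraries and 1 over the controls, a ratio of 271 (95% exact interval of counting 48.2 to 10700). Pdgfb, the endothelial factor that draws pericytes, rose from 0.313 ± 0.0892 to 1.52 ± 1.06 TPM. Cxcr4 (0.382 ± 0.178 and 1.27 ± 0.894 TPM), Unc5b (log2 fold change 0.81, standard error 0.28) and the abundant Vegfa (-0.22, 0.24) did not pass over all genes. The tip cell list lost its call with an estimated correlation (camera, adjusted p = 0.29 with an estimated correlation). Ltc4s, Ptp4a3, Trp53i11, Rflnb and Itga6, which stand in no fixed list, completed the 10 largest rises among called genes with a mean of at least 1 TPM in the higher group, with log2 fold changes of 2.62, 2.26, 2.15, 2.93 and 2.15.

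**Figure D2:**
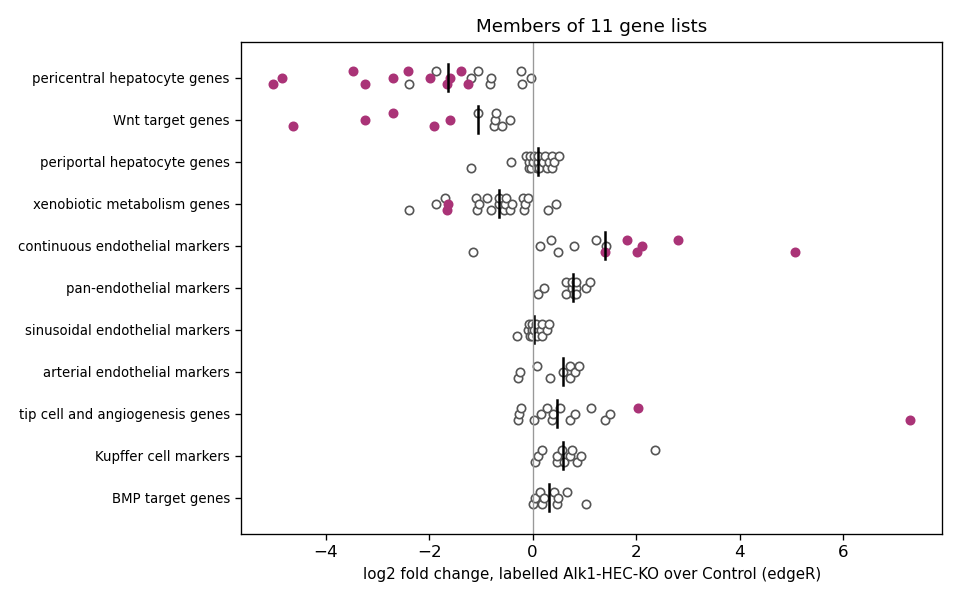
Log2 fold changes of labelled Alk1-HEC-KO over control (horizontal axis, edgeR) for the tested members of 11 lists, filled for called genes and open for others. Black bars are medians, -1.63 for pericentral genes, 1.40 for continuous endothelial and 0.02 for sinusoidal endothelial markers.

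Endothelial angiocrine factors, which act on neighbouring cells, gave 1 called gene of 13 tested, Pdgfb, and 2 that rose adjusted over the list alone. The pericentral WNT ligand gene Wnt9b had too few counts to be tested and was taken up after its values were seen. It averaged 0.285 ± 0.0963 TPM in controls and 0.0435 ± 0.0266 TPM in labelled knockout libraries, without overlap (exact permutation p = 0.0079), from 122 and 19 counts in all. Wnt2 (-0.91, standard error 0.47) and Rspo3 (-0.63, 0.33), which also activate the WNT pathway in hepatocytes, did not pass. Nos3 (1.06, 0.33), the endothelial nitric oxide synthase gene, rose adjusted over the list alone (edgeR, adjusted p = 0.043) and did not pass over all genes (edgeR, adjusted p = 0.33). Dll4 (0.73, 0.39) and Bmp4 (0.59, 0.27) passed neither way. Hgf, Bmp2, Bmp6, Angpt2 and Inhbb had log2 fold changes of 0.20, 0.09, 0.12, 0.02 and 0.30, and Dkk3 and Jag1 of -0.27 and -0.22. Edn1 and Il6, too low to be tested by edgeR and also taken up after their values were seen, did not pass an exact permutation test (p = 0.47 and 0.17). The list was not called (camera, adjusted p = 0.11).

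BMP target genes were not lower in whole liver. Endothelial cells are a small part of it, so these levels do not show how endothelial cells responded. None of 10 tested members passed, over all genes or adjusted over the list alone, and all 10 pointed higher, with a median of 0.31. Hamp, the iron hormone hepcidin, averaged 1865 ± 854 TPM in controls and 3850 ± 1303 TPM in labelled knockout libraries (edgeR, adjusted p = 0.38). Hamp2, its close copy whose reads may be shared with it, had a log2 fold change of 0.50 with a standard error of 0.60. Id1 (0.48, 0.32), Id2 (0.40, 0.18) and Id3 (0.66, 0.29), direct SMAD targets, did not pass. Smad6, Smad7, Smad9, Atoh8 and Bambi lay at 0.00, 0.19, 0.15, 0.05 and 0.22. Of the untested members, all 4 of them taken up after their values were seen, Hey1 averaged 0.0896 and 0.240 TPM and Id4 0.105 and 0.169 TPM (exact permutation p = 0.0079 and 0.016), while Tmem100 and Hey2 did not differ by that test (p = 0.68 and 0.58). The list was called higher with the preset correlation and not with an estimated one (camera, adjusted p = 0.28 with an estimated correlation). Among 18 ligands and receptors of the family none passed over all genes, 1 rose adjusted over the list alone, and the list was not called (camera, adjusted p = 0.97).

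Xenobiotic metabolism genes, many of them pericentral, gave 2 falls among 23 tested members and 13 adjusted over the list alone. Gstm2, a glutathione transferase gene of a family with near-identical copies, fell from 100 ± 23.4 to 33.6 ± 10.8 TPM, and Cyp1a2 from 416 ± 76.7 to 144 ± 65.8 TPM. Cyp2c29 (-1.04, standard error 0.21) and Cyp2c54 (-1.09, 0.26), which share sequence with other Cyp2c genes, and the abundant Gstm1 (-0.52, 0.20) did not pass over all genes. The list's call was lost with an estimated correlation (camera, adjusted p = 0.094 with an estimated correlation). It was called in the other 21 of 22 alternatives, among them fry (adjusted p = 0.029), though most of these kept the preset correlation. No other metabolic list had a called member. The median log2 fold change was -0.33 over 24 cholesterol synthesis genes, -0.48 over 16 fatty acid synthesis genes, of which all pointed lower (15 when scaled by library totals alone), and -0.26 over 18 bile acid genes. These 3 lists were called lower with the preset correlation only (camera, adjusted p = 0.48, 0.59 and 0.28 with an estimated correlation), and 1 bile acid gene fell adjusted over the list alone. Fatty acid oxidation, hypoxia and glycolysis, iron handling, unfolded protein response, and complement and coagulation genes (20, 19, 17, 15 and 24 tested) had no called member, and none of these lists was called (camera, adjusted p = 0.97, 0.57, 0.11, 0.97 and 0.60).

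Markers of other liver cells had no called member. All 12 Kupffer cell markers pointed higher with a median of 0.59, and 5 rose adjusted over the list alone. Of 9 tested markers of recruited leukocytes 8 pointed higher with a median of 0.87, and 3 rose adjusted over the list alone. Labelled knockout libraries 4 and 5, which also had high Saa1, stood apart with leukocyte scores of 2.44 and 2.04, and the other 3 (1.02 to 1.26) lay near the controls (0.522 to 1.25). Both lists were called with the preset correlation only (camera, adjusted p = 0.15 and 0.28 with an estimated correlation). Fibrosis and matrix genes (20 tested, median 0.44, 2 rose adjusted over the list alone) were likewise called only with the preset correlation (camera, adjusted p = 0.61 with an estimated correlation). Their score was 3.87 in labelled knockout library 4 and 2.09 to 2.46 in the other 4, against 2.12 to 2.62 in controls, and the list turned direction without library 4. Stellate cell, smooth muscle, cholangiocyte, erythroid and proliferation lists (13, 7, 6, 7 and 16 tested) were not called (camera, adjusted p = 0.74, 0.42, 0.40, 0.11 and 0.61), although 1 cholangiocyte marker rose adjusted over the list alone. Male-biased liver genes (13 tested, median -0.36) were called lower with the preset correlation only (camera, adjusted p = 0.48 with an estimated correlation). The female-biased, sex chromosome, and adipose and pancreas lists had only 2, 4 and 3 tested members and no set test.

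Signs of inflammation varied between libraries of both groups, while the handling sign Fos was high in control libraries only. Saa1, an acute phase protein, and Fos, an immediate early gene, were chosen after their values were seen. Saa1 stood at 6586 TPM in control library 4 and at 6733 and 13330 TPM in labelled knockout libraries 4 and 5, and at most at 874 TPM elsewhere. The 20 acute phase genes had a median of 0.64 and no called member (camera, adjusted p = 0.66 with an estimated correlation, called with the preset one). Fos stood at 27.6 and 24.2 TPM in control libraries 1 and 2 and at most at 4.92 TPM elsewhere. All 13 immediate early and heat shock genes pointed lower (12 when scaled by library totals alone), none was called, and the list's call was lost with an estimated correlation (camera, adjusted p = 0.29 with an estimated correlation). The 15 circadian clock genes had a median of -0.29 and the same loss (camera, adjusted p = 0.29 with an estimated correlation). Mitochondrial transcripts took 16.6% of counts in control library 3 and 5.82% in control library 5, with the labelled knockout libraries between 7.59% and 12.01%.

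Over all genes, 24 were higher and 22 lower in the labelled knockout libraries among 12872 tested, and 1087 had an unadjusted p under 0.05 where chance gives 644. Groups did not overlap in log2 CPM for any of the 46 called genes. That held for 1.68% of all tested genes against 0.794% by chance. Of the 33 tested lists 17 were called with the preset correlation and 3 with an estimated one, the pericentral, WNT target and continuous endothelial lists. No list score passed after Benjamini-Hochberg adjustment over the lists (exact permutation, lowest adjusted p = 0.095). Those 3 lists each had the smallest possible unadjusted p, 0.0079. The first principal component held 32.1% of the variance and did not part the groups fully, since control library 4 lay at 6.90 and labelled knockout library 1 at -8.32. The 3 libraries of the third run of file numbers, all labelled knockout, lay highest on it (11.25, 18.49 and 31.62, elsewhere at most 8.94). Correlations of log2 CPM ran from 0.960 to 0.978 within controls and from 0.948 to 0.970 within the labelled knockout group, and from 0.924 to 0.978 between the groups, with medians of 0.971, 0.959 and 0.960. Leaving out single libraries gave 18 to 40 genes higher and 15 to 43 lower, the most without labelled knockout library 1. Pdgfb, Slc22a3 and Cyp1a2 each lost their calls when any of 7 single libraries was left out (edgeR, adjusted p up to 0.11, 0.083 and 0.10), while their log2 fold changes stayed within 1.69 to 2.23, -2.99 to -2.15 and -1.85 to -1.48 over all such fits. Calls also ended for Axin2 with any of 6 libraries left out, Tbx3os1 with any of 5 and Cav1 with any of 4. The same held for Cd34 without control library 5 and Apln without control library 2. That last library held the only Apln count of the controls, so the contrast in counts did not shrink. With the run of file numbers as a covariate only 2 genes were called higher and 3 lower. That fit compares the groups within the first and second runs only, so the drop does not by itself show an effect of the runs. Without the 3 libraries with high Saa1 11 were higher and 19 lower, without the 2 with high Fos 7 and 10, and with DESeq2 82 and 70. Without the third run, the medians of the pericentral, WNT target and continuous endothelial lists stayed at -1.27, -0.94 and 1.13, while the fibrosis, acute phase, cholesterol and fatty acid synthesis lists turned direction and lost their calls. Within the first run Glul stood at 243 and 350 TPM in controls and 40.2 TPM in the labelled knockout library, within the second at 258, 246 and 320 against 30.2 TPM, and the third run held no control.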

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

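In a group of 5 libraries, a library was singled out when its gap to the nearest other library exceeded 0.71 of the group's range. Over 124 groups of values, 10 were singled out, where chance alone, at 1 in 20, gives about 6.2. The rule was fixed before the values were seen. Among control libraries, on the log2 CPM scale, control library 1 was high in Rflnb (-0.04, others at most -0.62) and in Hamp2 (5.77, others at most 4.56), and control library 2 in Emcn (1.19, others at most 0.49) and in Apln (-2.85, where the other libraries had no count). Control library 5 was low in Id1 (0.92, others at least 1.61) and control library 4 in Cyp2c54 (6.70, others at least 7.33). Among labelled knockout libraries, library 4 was high in Acvrl1 (2.44, others at most 1.67). Library 5 was low in Tnfrsf19 (-1.46, others at least 0.27), in Cyp2c29 (7.90, others at least 8.77) and in total estimated counts (20.91 M, others at least 21.15 M).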

How the results depend on the processing

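Fits with transcript length offsets, without high-Saa1 libraries and without high-Fos libraries were chosen only after results were seen. The replicate numbers gave no clear sign of pairing, though 5 pairs cannot exclude it. The 5 same-numbered pairs had correlations of 0.276, 0.084, -0.10, -0.038 and 0.108. Only in pair 1 did both libraries correlate best with their own number. With the replicate block 16 genes were higher and 24 lower, 14 and 18 of them shared with the fit without it, 19 lists were called, and Acvrl1 stood at 1.02.

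Counts of genes higher and lower were 24 and 22. They came to 68 and 51 without a low-count filter, where more genes were tested, and to 82 and 70 with DESeq2. They fell to 2 and 3 with the number run as a covariate and to 8 and 10 without the third number run. In both, only the labelled knockout libraries of the first and second runs bear on the group difference, fewer than in the main fit. At an adjusted p under 0.01 they were 8 and 14, and the lower count was 14 with glmTreat against 0.5. Both settings are stricter by construction and call fewer genes. On log2(TPM + 1) the lower count was 13, and the cause was not tested. Leaving out single libraries gave 18 to 40 higher and 15 to 43 lower. The highest pair came without labelled knockout library 1. The fit without the 3 libraries with high Saa1 gave 11 higher and 19 lower, and the fit without the 2 libraries with high Fos 7 and 10. Other scalings kept the counts within 20 to 27. Acvrl1 was positive and uncalled in all 25 alternatives (0.51 to 1.22, adjusted p from 0.12 to 1.0). Glul, Rhbg, Ly6c1 and Gstm2 passed in all 25.

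The 17 called lists became 3 with an estimated correlation and 4 with fry, and 14 to 20 when single libraries were left out. The pericentral, WNT target and continuous endothelial lists passed in all 22 alternatives. Turned directions are counted only where a call was involved, and 56 sign changes of uncalled lists and 39 of uncalled named genes are left out. Turned lists, with their adjusted p, were fibrosis without labelled knockout library 4 (0.62, with 0.000784 the lowest among left-out libraries), with the number run as a covariate fibrosis (0.72), acute phase (0.285), cholesterol (0.749), fatty acid synthesis (0.462) and male-biased genes (0.31), and without the third number run fibrosis (0.318), acute phase (0.089), cholesterol (0.929) and fatty acid synthesis (0.153). Without the high-Saa1 libraries venous (0.0302), stellate (0.00931) and fibrosis (0.829) lists turned. The cause was not tested. Sex as a covariate was not run.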

Other observations

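The genes of this paragraph and the next were called or looked up outside the naming rule and chosen after their values were seen, so they stand for no group. Jag2, a Notch ligand gene, rose from 0.0475 ± 0.0823 to 0.422 ± 0.161 TPM (SD, n = 5; edgeR, adjusted p = 0.0095), and Cd93, Jcad and Pcdh17 rose by log2 fold changes of 1.96, 1.51 and 2.10. Nos2, the inducible nitric oxide synthase gene, had 139 counts over the labelled knockout libraries and 1 over the controls, a ratio of 140 (95% exact interval of counting 24.7 to 5560). Among falls outside the rule, the receptor gene Hcrtr2 had 69 counts over the controls and 1 over the labelled knockout libraries, a ratio of 68.6 (11.9 to 2750).

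Igkc, the immunoglobulin kappa constant gene, rose from 8.46 ± 2.63 to 22.5 ± 6.73 TPM. Of other B cell genes looked up after this, none passed over all genes: Igha had a log2 fold change of 1.28, Cd79a 1.36, Cd79b 1.06, Ighd 0.98, Jchain 0.69 and Ighm -0.02. Cd79a rose adjusted over the recruited leukocyte list alone (edgeR, adjusted p = 0.016). The lambda light chain genes Iglc1, Iglc2 and Iglc3 had too few counts to be tested and averaged 0.295, 0.289 and 0.295 TPM in controls and 0.789, 1.32 and 1.13 TPM in labelled knockout libraries.

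Of the tests below, those of gene length and GC content and of other groupings were set down before their results were seen, and the others after. For the fall of pericentral genes, 10000 random lists matched on GC content, length and expression reached no median below -0.24, against -1.63. Without the 3 libraries with high Saa1 the median was -1.50, and with the number run as a covariate it was -1.37. Both were called with an estimated correlation, the second from the groups compared within the first and second runs only. None of these accounts for the whole fall. The genotype that the labels name stays untested.

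For the rise of continuous endothelial markers, a like rise of all endothelium is argued against by the difference between the continuous and sinusoidal scores. It was 1.30 larger in labelled knockout libraries (standard error 0.20, exact permutation p = 0.0079). That contrast was chosen after the continuous list had been called, so its p-value adds no separate support. Matched random lists reached a median of at most 0.54 against 1.40. The median stayed at 0.91 without the high-Saa1 libraries and at 1.13 with the number run as a covariate. The fit with that covariate compares the groups within the first and second runs only. Pieces of larger vessels taken along may add such markers. The smooth muscle score differed by -0.18 with a standard error of 0.43, too wide to decide. Labelled knockout libraries 1, 2, 3 and 5 had smooth muscle scores of at most 1.18, against 0.974 to 2.75 in controls. Their continuous scores were 2.84 to 3.44, against at most 2.27 in controls. This argues against vessels with smooth muscle as the source in those libraries. Labelled knockout library 4, with a smooth muscle score of 2.48, stays open. A change of endothelial state, or growth of continuous vessels, was not tested apart.

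For Acvrl1, a larger share of endothelial RNA could account for the higher level. Relative to the pan-endothelial score it was 0.29 higher (standard error 0.31, exact permutation p = 0.48). This leaves both that and a true rise open, and does not exclude a lower level per endothelial RNA. The continuous score rose by 1.33 and the sinusoidal by 0.03, against 0.99 for Acvrl1 in log2 CPM, so the answer depends on the score. A single mislabelled library is argued against by scoring each library on the lists called without it, with an estimated correlation: 0 lay on the other group's side of the midpoint. The smallest distance, 0.25, was that of labelled knockout library 1. That library was scored on 4 lists, control library 4 on 2 and the others on 3, so the distances do not share a scale. This score was the third version tried, after a score of called genes and a score of lists picked once they had been called, both dropped because the labels had chosen their genes. All 5 labelled knockout libraries exceeded every control in Acvrl1 TPM, though not in log2 CPM. On Acvrl1 alone, an exchange of the groups as a whole cannot be told apart from a deletion that leaves most of the transcript. The other genes, such as the pericentral ones, were not used to test an exchange.

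Among 100 of the 126 ways to split the 10 libraries into 5 and 5, the real one included, only 1 gave as many genes called higher as the real split, itself, with 24 against at most 13 in the others. The same held for lower genes, with 1 split, 22 against at most 13. Counts as large were thus rare among the splits run, which did not cover all 126. This makes chance unlikely for both counts without excluding it. The splits took no account of the runs of file numbers, and with the run as a covariate the counts were 2 and 3. For called lists, 17 of the 100 splits gave at least 17, with up to 20, so chance is not excluded for that count. With an estimated correlation 1 split gave 3, the real one, against at most 1.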
